A study of Homo sapiens with 6 samples.

How the data were processed

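Methylated RNA immunoprecipitation sequencing (MeRIP-seq) was done in MHCC97H, a human hepatocellular carcinoma cell line, after 48 h with 2 µM FB23-2, an inhibitor of the m6A eraser FTO, or with DMSO vehicle. There were 3 samples per treatment. Per the labels' protocols, poly(A) RNA was fragmented and an m6A antibody was used for the immunoprecipitation, and input and immunoprecipitated RNA were sequenced. The submitters' processing notes name HISAT2, Cuffdiff and the GRCh38 build. The peak caller, the versions of these tools and whether libraries kept strand information are not given in the sources used here.

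The authors deposited 2 peak tables, 1 per treatment. Their columns name no sample, so each table was taken as the treatment's pooled list, and no peak has a replicate check. Each row holds the peak's position and strand, a log2 fold change, a p-value and adjusted p-value, an annotation class and the gene the authors assigned. The log2 fold change and p-values per peak are the authors' own. Per the file headers the column is only called a log2 fold change; it is read here as immunoprecipitate over input, which the tables do not state. It was used only to describe, rank and filter peaks within a list. Read depth per sample is unknown, because the tables hold no counts, and binomial intervals below cover the counting of peaks only.

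Deposited start positions count from 0: they lay 1 base below the start of the assigned gene in 5661 DMSO and 5528 FB23-2 peaks and equalled it in 0. Positions are given here 1-based with both ends included. A peak's span includes any introns between its ends, since spans and not exon blocks were used. Gene names and annotation classes are those of the tables. Biotypes came from a RefSeq gene table for GRCh38.p14, used for names and biotypes only, which left 2523 of 16810 gene identifiers unmatched.

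A peak was called shared when it overlapped a peak of the other list on the same strand by at least 50% of the shorter of the pair, and list-only otherwise (bedtools 2.31.1). Shares carry exact (Clopper-Pearson) 95% intervals. Genes were matched by the deposited identifier. For each of 28 gene lists, FB23-2-only minus DMSO-only peaks per gene was placed among 10000 random lists of the same size. Random lists were matched on the number of peaks per gene, in bins of at least 100 genes, and drawn with replacement. The percentile describes these peak lists and is not a p-value. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

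The steps were tested on simulated data. With 79.9% of the 42813 DMSO peaks kept in a simulated second list and moved by up to 10% of their span, 100% of the kept peaks were called shared and 96.3% of the removed peaks list-only. A shift this small leaves most of each kept peak overlapped, so that 100% was fixed by the design. It checks only that the step ran as written, and larger differences in borders were not simulated. Among 16810 genes with 200 changed, 3% of 100 lists of 30 unchanged genes fell outside the central 95% of random lists, and 100% of 20 lists of 30 changed genes did. Of 20 lists with 10 changed genes among 30, 15% did, so a change in part of a list is mostly missed. The 100% of changed lists checks only that the step finds a change of the simulated size in every gene of a list. Other sizes of change per gene and other list sizes were not simulated. The real lists held from 2 to 77 genes with a peak, so these shares do not tell how small a change would be found in them.

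The groups, comparisons, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The rule names 10 genes always: FTO, ERBB3, TUBB4A, METTL3, METTL14, WTAP, ALKBH5, YTHDF1, YTHDF2 and YTHDF3. It then takes, per list, the 8 single-list genes with the most significant peak and the 5 genes with the most list-only peaks. The 5 genes with the most significant shared DMSO peaks and up to 4 members per gene list with the most significant list-only peak complete it; ties in p, which include all peaks deposited with a p of 0, went by fold. Not all of these genes are printed, and some results are not reported here. Genes outside the rule are said to be so. Alternatives were an adjusted p under 0.001, a fold of at least 4, other overlap rules, strand ignored, merged peaks, the 33470 most significant peaks per list (80% of the shorter), exon and UTR peaks, each gene counted once, and unmatched random lists. Terms of the KEGG column with 20 to 300 genes, and a strict threshold in 1 list alone with any overlap, were added after the data had been seen. Motif search and any test between samples were not run, for want of a genome and of values per sample here.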

Results

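MeRIP-seq, in which an antibody enriches RNA fragments that carry N6-methyladenosine (m6A), was used in MHCC97H liver cancer cells to look for targets of FB23-2 through its inhibition of FTO. There were 3 DMSO samples and 3 FB23-2 samples, and each treatment has 1 pooled peak list. The DMSO list held 42813 peaks in 16158 genes and the FB23-2 list 41838 peaks in 16003 genes, or 2.65 and 2.61 peaks per gene. The median span was 575 bases in both lists. Read depth is unknown, there are no replicates of a list, and no difference between the lists could be tested against the spread between samples.

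The genes in the series title had peaks under both treatments. ERBB3, a receptor tyrosine kinase of the EGFR family, had 4 peaks in each list, of which 2 were shared and 2 were found in that list only. Both FB23-2-only peaks lay in coding exons, at chromosome 12, 56083885 to 56085101 (log2 fold 1.45) and 56085127 to 56086521 (log2 fold 1.60). These 2 nearly abut and can be 1 region cut in 2. Both DMSO-only peaks were annotated to the 3' UTR, at 56096427 to 56097099 (log2 fold 1.06) and 56098739 to 56099655 (log2 fold 0.93). Both lie upstream of the shared peaks at the gene's 3' end, and the deposited class was not checked against other transcripts of the gene. No shift from 3' UTR to coding exons can be read from these classes. The second of them ends just before a shared DMSO peak begins, so its standing as a separate peak is uncertain. The shared ERBB3 peaks lay at the 3' end of the gene: the DMSO peak at 56099681 to 56102419 had a log2 fold of 1.40 in its list, and the FB23-2 peak at 56101595 to 56102244 had 2.07 in its own. The last peak, at 56103295 to 56103505 in both lists, had 0.90 under DMSO and 1.44 under FB23-2. TUBB4A, a beta-tubulin, had 2 peaks in each list and all were shared. Its 3' UTR peak began at chromosome 19, 6494319 in both lists, with a log2 fold of 2.47 under DMSO and 3.24 under FB23-2; the other, from 6495769, had 2.32 and 1.84. These folds come from separate lists and show no change by themselves. The ERBB3 list-only peaks depend on the settings: none of these 4 reached a fold of 4. At that threshold ERBB3 had 0 DMSO-only and 1 FB23-2-only peaks, the latter being the shared peak of 2.07, whose DMSO partner fell below it. It had 0 and 1 with equal numbers of top peaks, 1 and 2 at an adjusted p under 0.001 and 3 of each with reciprocal overlap. The shared state of TUBB4A also depends on the settings: 1 DMSO-only and 0 FB23-2-only peaks were found at a fold of at least 4 and with equal numbers of top peaks, and 1 of each with reciprocal overlap.

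**Figure D1:**
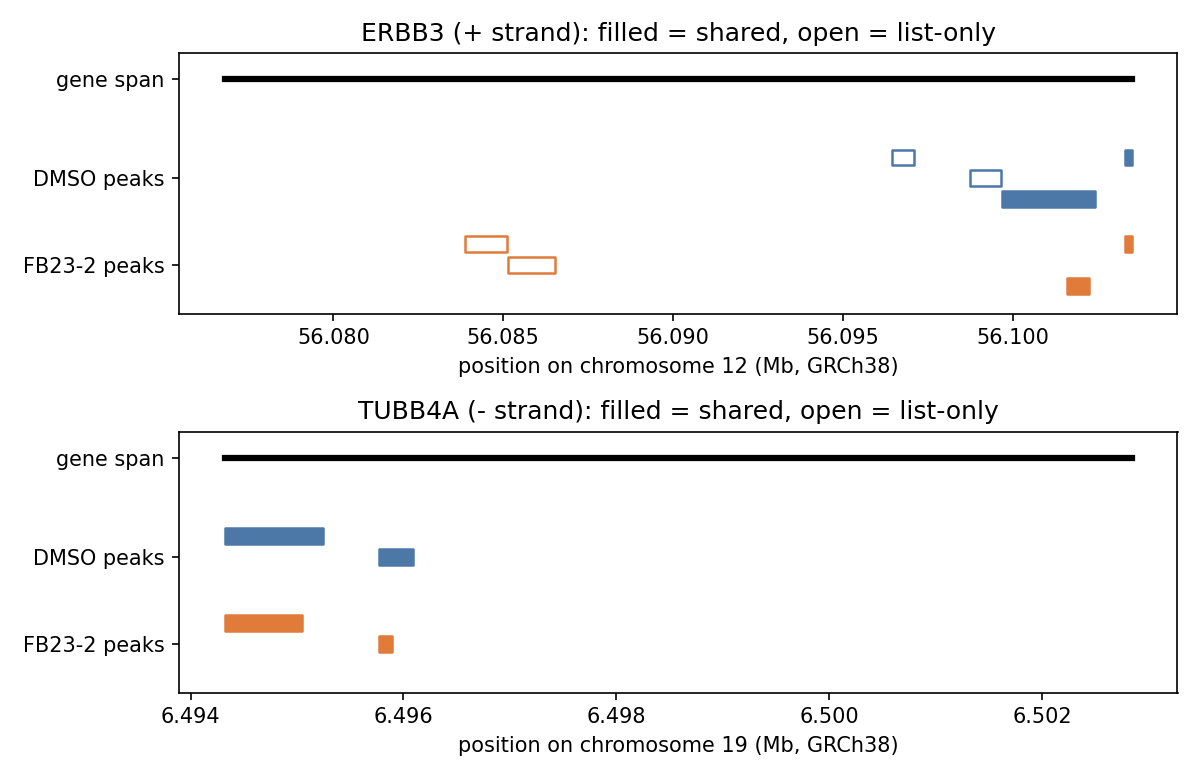
Peaks of ERBB3 (top) and TUBB4A (bottom) along the chromosome in megabases (GRCh38), for the DMSO list (blue) and the FB23-2 list (orange), with the gene span in black and rows offset only for legibility. Filled boxes are shared peaks and open boxes are list-only peaks; ERBB3 has 2 open boxes in each list and TUBB4A has 0.

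Among the m6A machinery, METTL3, the catalytic writer, had 7 DMSO and 3 FB23-2 peaks. Its 4 DMSO-only peaks had log2 folds from 0.82 to 0.99, while its 5' UTR peak at chromosome 14, 21508203 to 21511331, was identical in position in both lists (2.24 and 2.34). FTO itself had 2 DMSO peaks, both shared, and 1 FB23-2-only peak in an intron at chromosome 16, 54072377 to 54072501 (log2 fold 1.26). WTAP, a writer subunit, had 1 FB23-2-only peak, in the 5' UTR (log2 fold 1.25), beside a shared 5' UTR peak of 4.53 under DMSO and 4.55 under FB23-2. METTL14, the eraser ALKBH5 and the readers YTHDF1, YTHDF2 and YTHDF3 had shared peaks only. The 3' UTR peak of METTL14 had a log2 fold of 2.96 in both lists, and that of YTHDF2 had 3.75 and 3.83.

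Among shared DMSO peaks tied at a deposited p of 0, the named genes are those with the highest DMSO folds. PMEL, a melanosome protein, had a single peak with a log2 fold of 9.23 under DMSO and 9.09 under FB23-2, at chromosome 12, 55954105 to 55966087 in both. The calpain subunit CAPNS1 (6.33 and 6.24) and NCBP2AS2 (5.77 and 5.65) were among them, as was the SUMO protease SENP3, whose 5' UTR peak had 6.86 under DMSO. By the overlap rule, 34206 of 42813 DMSO peaks (79.9%, 95% interval 79.5 to 80.3) and 34611 of 41838 FB23-2 peaks (82.7%, 82.4 to 83.1) were shared, leaving 8607 DMSO-only and 7227 FB23-2-only peaks. Of these, 8092 and 6677 overlapped no peak of the other list by a single base. Of the peaks with a deposited p of 0, 4681 of 4701 under DMSO (99.6%, 99.3 to 99.7) and 4505 of 4506 under FB23-2 were shared, and in the least significant 10% 36.3% (DMSO) and 45.8% (FB23-2). That last part begins at a deposited p of 0.00135 under DMSO and 0.000431 under FB23-2, so these shares cover peaks of unlike strength. Which list shared more turned with both lists cut at a fold of at least 4, with 84.8% of DMSO and 83.7% of FB23-2 peaks. A partner below that fold no longer counted there. At an adjusted p under 0.001, 37989 DMSO and 38467 FB23-2 peaks were left, and 83.5% and 83.6% of them were shared. The larger number of DMSO-only peaks in the full lists therefore depends on the weaker calls.

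**Figure D2:**
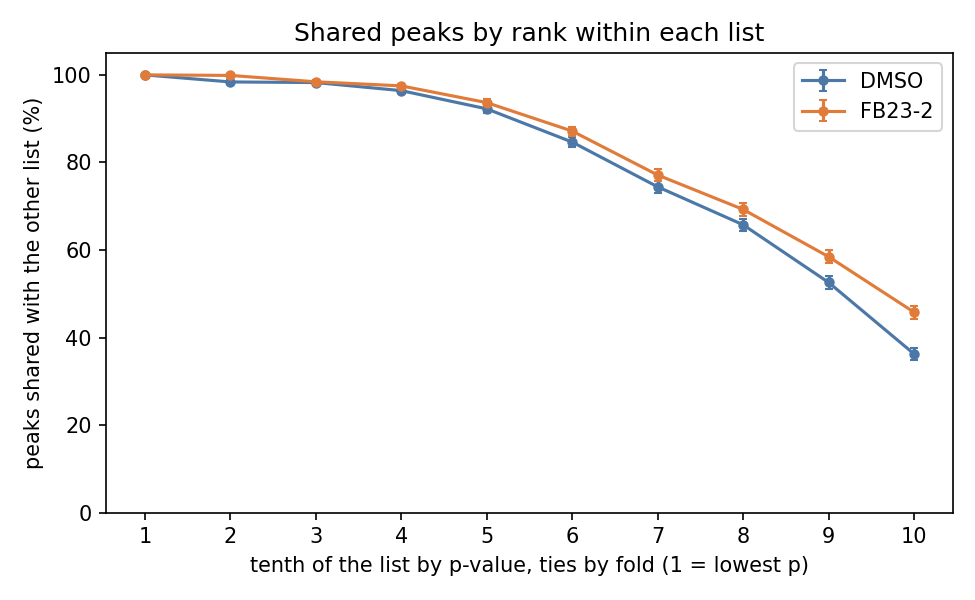
Percent of peaks shared with the other list (vertical axis, with exact 95% intervals for counting) against rank in the list by p-value, with ties ordered by fold, in 10 equal parts with 1 the lowest p, for DMSO (blue) and FB23-2 (orange). Part 1 ends inside the peaks tied at a p of 0, so its 100% leaves out the 20 DMSO-only and 1 FB23-2-only peaks with that p. Sharing is 36.3% for DMSO and 45.8% for FB23-2 in the last part. The same part covers unlike ranges of p in each list.

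List-only peaks had lower folds than shared peaks on the median of each list. Their median log2 fold was 1.03 against 1.53 for shared peaks under DMSO, and 1.10 against 1.52 under FB23-2, and their median span was 225 bases in both lists. RPL8, a ribosomal protein, was an exception in significance: its only peak (chromosome 8, 144789765 to 144790356, 3' UTR, log2 fold 1.06) was DMSO-only with a deposited p of 0. The single peaks of the ribosomal protein RPS27 (1.03) and of C19orf33 (1.27), both in 3' UTRs, were also DMSO-only with a p of 0. RPL8, RPS27, PGAM1 and TUBB4A have named pseudogenes, with which their reads can be shared, so their peaks are uncertain in that respect. Other genes named here can have the same limit. Of the 70 genes with a DMSO-only peak at a p under 1e-100, 33 have a named pseudogene.

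Peaks lay mainly in 3' UTRs in both lists, 57.3% under DMSO and 57.3% under FB23-2. Shared peaks were in 3' UTRs in 60.5% (DMSO) and 60.4% (FB23-2), against 44.5% (95% interval 43.5 to 45.6) of DMSO-only and 42.3% (41.1 to 43.4) of FB23-2-only peaks. Coding exons held 20.1% of DMSO-only and 19.3% of FB23-2-only peaks against 11.1% and 11.4% of shared ones. Introns held 9.97% and 11.1% against 3.44% and 3.29%. The 5' UTR share was 10.6% (9.96 to 11.3) among DMSO-only and 13.6% (12.8 to 14.4) among FB23-2-only peaks. Over all peaks of each list it was 11.7% and 12.2%. This share was not run in other settings, and with 1 list per treatment it shows no effect of FB23-2. FADS1, a fatty acid desaturase, had 3 FB23-2-only peaks annotated to the 5' UTR and 1 in a coding exon.

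**Figure D3:**
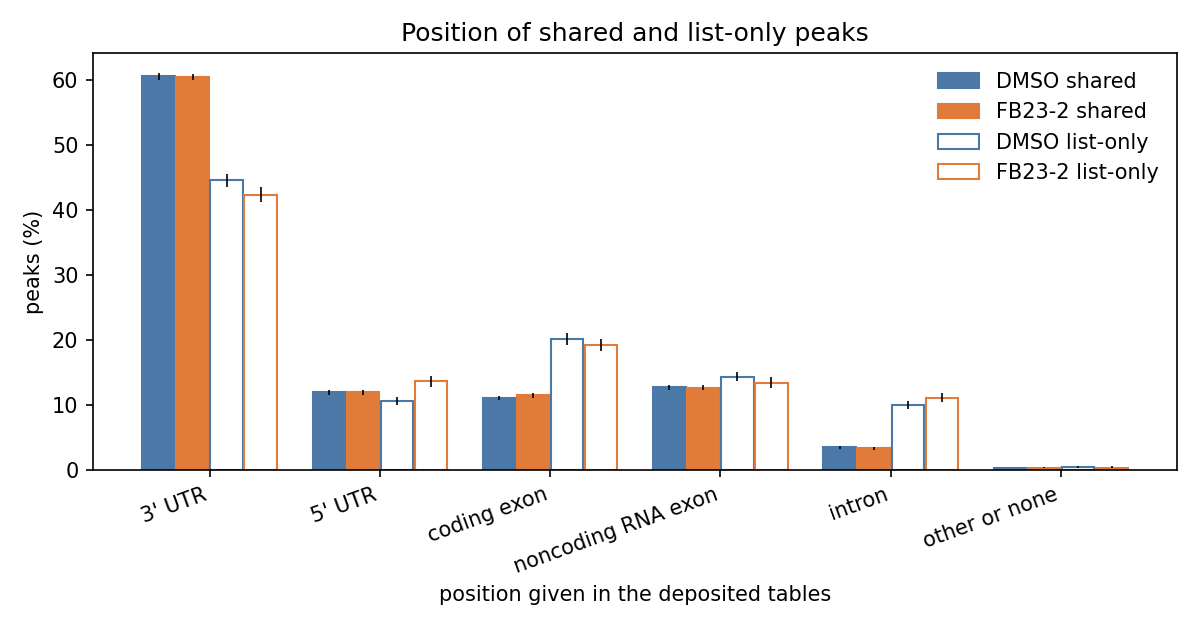
Percent of peaks (vertical axis, with exact 95% intervals for counting) per annotation class of the deposited tables, for shared (filled) and list-only (open) peaks of DMSO (blue) and FB23-2 (orange). 3' UTRs hold 60.5% and 60.4% of shared peaks but 44.5% and 42.3% of list-only peaks.

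The next comparison asks which transcripts carried a peak under 1 treatment only. PGAM1, a glycolytic enzyme, had 2 FB23-2-only peaks and no DMSO peak, the more significant in the 3' UTR at chromosome 10, 97433230 to 97433444 (log2 fold 1.33). EGR2, an immediate early transcription factor, had 3 FB23-2-only peaks, up to a log2 fold of 2.99 in a coding exon. FGA and FGB, the fibrinogen alpha and beta chains, each had 1 FB23-2-only peak (4.38 and 2.02), as did the interferon signalling factor IRF9 (1.19). The other hepatocyte genes with peaks in 1 list only, AMBP with 1 peak and the gluconeogenic enzyme PCK1 with 3, had them under DMSO; both were chosen after their values were seen. On the DMSO side RPL8, RPS27 and CDC20, an activator of the anaphase-promoting complex (1.01), had 1 peak each and none under FB23-2. Of 16810 genes, 15351 (91.3%) had a peak in both lists, 807 in the DMSO list only and 652 in the FB23-2 list only. Of the single-list genes 85.4% and 89.1% had 1 peak, and 38.3% and 41.0% had no biotype in the reference table, against 12.7% of genes in both lists. Among genes with a biotype, 61.2% of the 498 DMSO-only and 57.4% of the 385 FB23-2-only genes were protein coding, against 89.9% of the 13404 in both lists.

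Several of the most significant single-list genes had peaks that the other list assigned to another gene. The DMSO peak of CDC42EP2 overlapped an FB23-2 peak assigned to POLA2, that of BIVM-ERCC5 one assigned to ERCC5, and that of SNORA17B one assigned to SNHG7. The FB23-2 peaks of INTS5 overlapped a DMSO peak assigned to AP001458, 2 of the 3 peaks of SCO2 DMSO peaks of TYMP (the other was FB23-2-only), and those of JTB and RBM34 peaks assigned to RAB13 and ARID4B. In all, 53 DMSO-only and 58 FB23-2-only genes had such an overlap, and 754 and 594 had none. With both lists cut at a fold of at least 4 the order turned, with 967 DMSO-only and 1017 FB23-2-only genes. These include genes whose peak in the other list fell below that fold. The order did not turn among single-list genes without such an overlap that had a peak at an adjusted p under 0.001. There were 581 DMSO-only and 500 FB23-2-only ones, in a check added after the data had been seen.

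Among genes with peaks in both lists, the long noncoding RNA PAX8-AS1 and SYNE1, a nuclear envelope spectrin-repeat protein, had the most DMSO-only peaks, 13 each. They had 6 and 3 FB23-2-only peaks, and in all 18 and 24 DMSO and 11 and 14 FB23-2 peaks. DST, a cytoskeletal linker, had the most FB23-2-only peaks, 12 of 30, beside 5 DMSO-only ones of 20. HOOK3, a microtubule adaptor, had 7 of 10 beside 2 of 4. Such counts favour genes with many peaks. Some others in these rankings were more even, with 7 and 7 in NEBL and 7 DMSO-only and 9 FB23-2-only peaks in FARP1. All peaks were shared in 8011 of the 15351 genes (52.2%), while 5026 had a DMSO-only peak, 4537 an FB23-2-only peak and 2223 both.

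Long noncoding RNAs with m6A formed the only list of 28 outside the central 95% of random lists, where 1.4 would fall by chance. Its 11 genes with a peak had 9 DMSO-only and 18 FB23-2-only peaks, a difference of 0.818 per gene (percentile 99.0). NEAT1, a paraspeckle RNA, had 6 DMSO-only and 9 FB23-2-only peaks, PVT1 3 and 5, TUG1 0 and 2, and MALAT1 and NORAD 0 and 1 each. At a fold of at least 4 the list's percentile fell to 26.9 and 0 lists stood outside. Cholesterol and fatty acid synthesis, with 7 DMSO-only and 14 FB23-2-only peaks in 30 genes, lay at percentile 95.2, inside the range. By themselves its DMSO-only peaks lay at percentile 2.1 and its FB23-2-only peaks at 66.1. In that list FADS1 had 0 and 4, and CYP51A1, a sterol demethylase, and SREBF1, a regulator of lipid synthesis, had 0 and 1. The mevalonate kinase MVK had 2 and 0.

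The lists closest to the title lay inside the range. In 15 of the 28 lists the percentile lay on the other side of 50 in at least 1 other setting, 13 of them at a fold of at least 4, and members are named for the significance of a list-only peak unless said otherwise. ERBB, PI3K and MAPK signalling had 30 DMSO-only and 31 FB23-2-only peaks in 53 genes (percentile 76.9); NRAS and PIK3R2 had 1 FB23-2-only peak each, and GAB1, chosen after its values were seen, 2 DMSO-only peaks. Tubulins and tubulin folding had 14 and 17 in 39 genes (83.4). In the ERBB and tubulin lists, DMSO-only peaks by themselves lay at percentiles 6.52 and 4.95, and FB23-2-only peaks at 30.6 and 38.7. The percentiles of the difference above 50 thus came with few DMSO-only peaks, not with many FB23-2-only ones. FTO substrates reported in cancer cells had 5 and 3 in 16 genes (42.0), with PKM, pyruvate kinase, at 1 and 0 and GNAO1 at 0 and 2. The m6A writers had 5 and 9 (90.6), with METTL3 at 4 and 0, METTL16 at 0 and 2 and ZCCHC4, chosen after its values were seen, at 0 and 4, the erasers 0 and 1 (77.2), and the readers 10 and 5 (28.8), with FXR1 at 3 and 0.

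For growth and death, cell cycle and mitosis had 23 DMSO-only and 14 FB23-2-only peaks (percentile 25.0). TOP2A, a DNA topoisomerase, had 3 and 0, and PCNA 0 and 1. Apoptosis had 20 and 11 (15.9), with 3 and 0 in CASP10 but 3 and 4 in CFLAR. The p53 targets had 16 and 10 (28.4), DNA repair 38 and 32 (49.2) and autophagy 29 and 19 (15.0). Histone and chromatin regulators had 70 and 56 (41.8), with 4 and 0 in the remodeller CHD4 but 0 and 1 in BRD2. Immediate early genes had 13 and 10 (41.0), and WNT, NOTCH and Hippo 17 and 21 (85.2). In the WNT, NOTCH and Hippo list, DMSO-only peaks by themselves lay at percentile 1.59 and FB23-2-only peaks at 26.2. Epithelial to mesenchymal transition had 17 and 15 (58.8).

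For metabolism and translation, glycolysis had 11 DMSO-only and 5 FB23-2-only peaks (percentile 16.9), and pyrimidine and purine synthesis 17 and 13 (38.2). ATF4 and unfolded protein response had 12 and 15 (82.2), with 0 and 2 in the transcription factor ATF4 but 1 and 0 in HSP90B1. Cytosolic ribosomal proteins had 36 and 23 (20.5), mitochondrially encoded mRNAs 0 and 1 (75.1) and interferon response 9 and 11 (78.1). Liver cancer and progenitor genes had 16 and 8 (16.8), with 4 and 0 in the keratin KRT8 but 0 and 1 in the keratin KRT18. Of the 45 hepatocyte genes 14 had a peak, with 7 and 4 list-only peaks (23.9, but 96.1 at a fold of at least 4). Of markers of other cell types, those of fibroblasts and stellate cells had 12 and 6 in 9 genes (13.5), of endothelial cells 2 and 0 in 2 genes (4.61) and of leukocytes 3 and 3 in 4 genes (56.1).

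**Figure D4:**
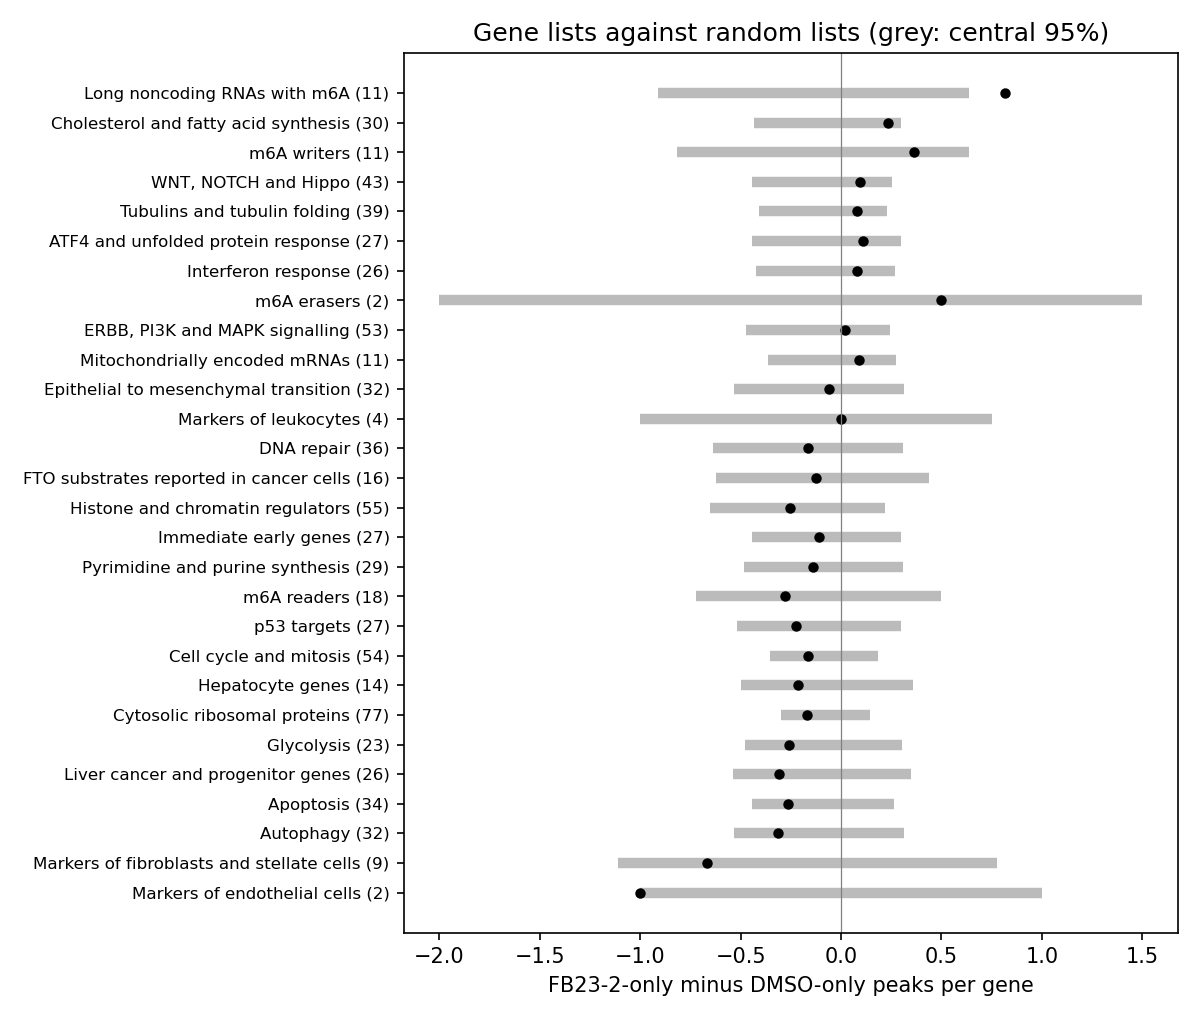
FB23-2-only minus DMSO-only peaks per gene (horizontal axis) for the 28 gene lists, with the number of genes with a peak in brackets. Points are the lists and grey bars the central 95% of 10000 random lists; only the long noncoding RNAs, at 0.818, lie outside.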

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

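The strict threshold in 1 list alone was chosen after the data had been seen. At a fold of at least 4, the lists shrank to 12514 DMSO and 12724 FB23-2 peaks in 9215 and 9265 genes, with 84.8% and 83.7% of peaks shared. There were then 1017 FB23-2-only genes, some of them with a DMSO peak below that fold, and 0 gene lists outside the random range. 3' UTRs then held 52.9% of shared and 41.7% of list-only DMSO peaks, and 52.8% and 35.8% for FB23-2; the percentile of the long noncoding RNAs reversed to 26.9. The shared share (DMSO, then FB23-2) was 83.5% and 83.6% at an adjusted p under 0.001, 85.2% and 86.2% with equal numbers of top peaks, 81.1% and 84.0% with any overlap, 64.4% and 65.9% with reciprocal overlap, 81.1% and 83.8% with strand ignored, and 86.3% and 87.3% with an adjusted p under 0.001 in 1 list and any overlap. With equal numbers of top peaks, 3' UTRs held 61.6% and 61.4% of shared peaks and 45.9% of DMSO-only peaks. With each gene counted once they held 66.2% and 65.7% of shared peaks and 43.4% and 39.6% of list-only peaks. In every setting run, list-only peaks were less often in 3' UTRs than shared ones. Fewer peaks by construction explain the smaller lists; otherwise the cause was not tested. Of all comparisons that answer a question, 31 moved outside their limits and 25 stayed within them. The limits were the 95% interval of the main setting for a share and 1.5 times for a count. Of the counts for single genes 26 stayed within 1.5 times and 10 moved. Of the list percentiles 110 stayed inside or outside the central 95% as before, but many crossed 50: 6 of 28 at an adjusted p under 0.001, among them p53 targets (28.4 to 89.4), 13 of 27 at a fold of at least 4, among them autophagy (15.0 to 85.8), hepatocyte genes (23.9 to 96.1) and leukocyte markers (56.1 to 4.32), and 1 of 28 with any overlap.

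No paired analysis was possible because the columns of the deposited tables carry no samples or replicate numbers. Leaving out replicates, pseudocounts, filters on low values, other tests per sample, exon blocks and the motif were not run. Depth is unknown, so whether a list-only peak reflects fewer reads under the other treatment could not be tested.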

Other observations

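All tests in this part except those of pseudogenes and of nearby opposite-strand peaks were chosen after the result they measure was seen, as were the KEGG terms.

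Among the KEGG terms in the tables, biosynthesis of unsaturated fatty acids had 4 DMSO-only and 17 FB23-2-only peaks in 24 genes, at percentile 99.9 of matched random lists. FADS1 had 0 and 4, and the sterol carrier SCP2, the elongation enzyme HSD17B12 and the dehydratase HACD4 had 0 and 2 each; the last 3 were chosen after their values were seen. Fatty acid elongation, which shares 15 of its 24 genes with that term, had 3 and 12 (99.1), non-alcoholic fatty liver disease 49 and 68 in 133 genes (99.3) and C-type lectin receptor signalling 42 and 58 in 77 genes (99.1). Other lipid terms lay inside the range, such as glycerophospholipid metabolism with 48 and 37 in 71 genes (26.8). Type II diabetes mellitus lay at the other end, with 28 DMSO-only and 9 FB23-2-only peaks in 33 genes (percentile 0.640), among them 3 and 0 in IRS1, the insulin receptor substrate, and 2 and 0 in MTOR, also named after their values were seen. Only 5 of 264 terms lay outside the central 95%, where 13.2 would by chance. That count does not judge the most extreme term by itself, and terms share genes. No term was tested against the number of terms looked at, so nothing is concluded from any of them.

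List-only peaks lay low in the ranking of their own list, with 36.3% of peaks shared in the least significant 10% under DMSO and 45.8% under FB23-2. Those parts cover unlike ranges of p, so the shares are not set against each other. Only 5.98% of DMSO-only and 7.61% of FB23-2-only peaks touched a peak of the other list, so partial overlap accounts for few of them. Whether differently drawn borders play a part stays open. Peaks with larger overlaps were called shared by definition, and a piece cut off beside a peak would touch nothing. Mirrored opposite-strand peaks made up 0.697% and 0.470% of list-only peaks. Calls near the authors' threshold stay open, since the ranking that would show them is the pattern itself. An effect of FB23-2 on weakly methylated sites also stays open and untested, as each treatment has 1 list.

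Very significant peaks were more often DMSO-only. Of peaks with a p under 1e-100, 79 of 9166 were DMSO-only and 9 of 8870 FB23-2-only; the former lay in 70 genes, 12 of them ribosomal proteins, and 78 had a log2 fold under the median of shared peaks of that significance (2.51). A larger supply of low-fold peaks under DMSO is argued against, since 213 DMSO and 201 FB23-2 peaks of that significance had a log2 fold under 1. Of these, 39 DMSO peaks (18.3%, 13.4 to 24.2) and 5 FB23-2 peaks (2.49%, 0.813 to 5.71) were list-only. The intervals treat peaks as independent, though some genes hold more than 1. This cut covers 39 of the 79 DMSO-only peaks. Reads shared with pseudogenes stay open, since 47.1% of the 70 genes (35.1 to 59.4) have a named pseudogene against 17.1% of genes with shared peaks of that significance, but 37 have none. The treatment and the scaling of the libraries also stay open, without counts per sample.

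Some peaks on opposite strands mirrored each other. The DMSO list held 566 pairs that overlapped by 50% of each peak, whose log2 folds correlated across pairs with r = 0.790, against 0.196 with the nearest opposite-strand peak not overlapped, a difference of 0.594; for FB23-2 it was 0.589 over 527 pairs. Pairs are not independent replicates. This is consistent with reads counted on both strands, and no biological explanation was tested. Whether libraries kept strand information is not given in the sources used here.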
